A study of Homo sapiens with 9 samples.

How the data were processed

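RNA sequencing measured gene expression in 9 libraries of LoVo cells, a line established from a human colorectal adenocarcinoma. The labels place 3 libraries each in a control group infected with a control lentivirus (shNC) and in groups infected with a lentivirus carrying one of a pair of short hairpin RNAs against NSD2 (shNSD2#1 and shNSD2#2). A short hairpin RNA is processed into a small interfering RNA that lowers the messenger RNA it matches. The labels describe extraction of total RNA with TRIzol and removal of genomic DNA with DNase I, and they number the libraries of a group as biological replicates. They do not say whether replicates came from separate infections or culture dishes, so p-values measure the spread between these libraries, which may be technical.

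The deposited tables hold an estimated count and a TPM value for each gene and library, per the file headers. The estimated counts are not normalized, and 61.2% of the nonzero count values are whole numbers. The TPM values were scaled by the authors for gene length and library size, per the file headers. The tables also hold the authors' group means in 3 columns, and a gene length, which served as the length in the check of length trends. The submitters' processing notes name fastp, HISAT2, StringTie and DESeq2, without versions or roles, and the genome build hg18. The program that made the counts, the annotation release and the use of strand are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense neighbour cannot be told apart. The column names of the tables begin with Si where the labels speak of lentiviral hairpins, and each column was matched to its library through the spreadsheet column letter in the labels.

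Each table has 61057 rows with an identifier, and 1 line per table holds no values and is not reported here. Of these rows, 387 carry a StringTie locus number in place of a gene name. They stayed out of library sizes and tests, and held 3.78% of the counts in shNC and 6.33% in the knockdown libraries on average. The other 60670 rows carry Ensembl identifiers, of which 96.3% occur in GENCODE 29, an annotation of GRCh38. Gene types and the coordinates given below come from that annotation, not from the deposited tables.

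Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group were kept (16376 genes, of which 13217 are protein-coding), and libraries were scaled with TMM factors. All 9 libraries entered one quasi-likelihood fit (glmQLFit with robust dispersions, glmQLFTest) with a mean per group and no covariate. The 4 contrasts were shNSD2#1 against shNC, shNSD2#2 against shNC, the mean of both hairpins against shNC, and shNSD2#2 against shNSD2#1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold, and "rose" and "fell" refer to such calls. Unless stated otherwise, fold changes and adjusted p-values of genes come from this edgeR fit, standard errors (SE) are those of the log2 fold change, and CPM are counts scaled by library size and TMM factor. Knockdown means are taken over the 6 libraries of both hairpins.

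Before the data were examined, 28 gene lists were fixed, along with the rule for the genes named, the test of each comparison and most alternatives. The rule names NSD2, TIAM1 and RAC1. It then takes the 10 highest and 10 lowest log2 fold changes among genes with a mean log2 CPM of at least 1 that were called with both hairpins in one direction, leaving out clone-based names. It adds up to 4 members per list with the smallest adjusted p, and the 5 highest and 5 lowest genes called between the hairpins. Genes withheld for evaluation that this rule would take are not reported here. Lists with at least 5 tested members were compared with all other tested genes by camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The same test was repeated with the correlation estimated from the data, and fry from limma tested whether the members of a list moved, on balance, one way. Fry does not compare a list with the other genes. As 50.3% of tested genes were called for the mean of both hairpins, a fry call alone does not set a list apart. Camera and fry p-values were adjusted over the 25 lists tested.

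The steps were tested on simulated data. Counts were drawn from the shNC means and library sizes, with 50 genes changed at each of 4 fold sizes and the 36 tested genes of the G2/M and mitosis list raised by 0.3 on the log2 scale. In the contrast of the mean of both hairpins against shNC, run on 16027 genes, the fit recovered 68% of genes changed by 0.3 on the log2 scale, 76% at 0.5, 92% at 1 and 100% at 2. It called 15 of 15791 unchanged genes in that contrast. For shNSD2#1 against shNC, run on the same 16027 genes, recovery was 54% at 0.3 and 92% at 1. In the data, 50.3% of tested genes were called for the mean of both hairpins, a far larger share than the simulation changed. The simulated rates of recovery and of false calls therefore do not carry over to the data.

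Library totals ran from 20464639 to 27151364 counts over all rows, and the biological coefficient of variation was 4.67%. Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 1.76 to 6.47, which does not tell biological from technical spread. A comparison of shares of counts between shNC and knockdown used a two-sided exact permutation test over the 84 ways to choose 3 of 9 libraries.

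The alternatives were DESeq2 1.42.0 size factors or its Wald test, upper quartile factors, library sizes alone, no filter or a filter at 5 CPM in 3 libraries, and limma on log2(TPM + 1) or log2(TPM + 0.1) for genes with a TPM of at least 1. Further alternatives were a fit of the compared groups alone, a fit with the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library. Keeping the unnamed loci, removing ribosomal RNA and mitochondrially encoded genes, and removing trends with GC content and length by loess offsets were added after seeing the data. A comparison of gene ontology terms, taken from the deposited annotation, was also chosen after seeing the data. Figures were drawn with matplotlib in Python.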

Results

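The series asks, by its title, how methylation of TIAM1 by NSD2 bears on Rac1 signalling and metastasis, and its design text asks which genes and pathways differ once NSD2 is lowered. NSD2 is a histone methyltransferase that dimethylates lysine 36 of histone H3. TIAM1 is a guanine nucleotide exchange factor that activates the small GTPase RAC1, a regulator of actin and cell migration. The data are gene-level counts of 9 LoVo libraries, 3 each of shNC, shNSD2#1 and shNSD2#2. Totals over named genes and unnamed loci were 20872306 to 27151364 counts in shNC, 20464639 to 25509941 in shNSD2#1 and 20743079 to 26375416 in shNSD2#2.

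NSD2 messenger RNA was lower in each of the 6 knockdown libraries than in each shNC library. NSD2 (ENSG00000109685; GRCh38 chromosome 4, 1871424 to 1982207, plus strand, protein-coding gene) had 220 ± 4.78 CPM in shNC, 164 ± 3.67 in shNSD2#1 and 155 ± 1.02 in shNSD2#2 (SD, n = 3 each). It fell by 0.43 on the log2 scale with shNSD2#1 (SE 0.034, edgeR adjusted p = 1.01e-09) and by 0.51 with shNSD2#2 (SE 0.035, edgeR adjusted p = 3.49e-11). Over both hairpins the level fell by 27.7%, and the hairpins did not differ by the edgeR test (log2 difference -0.08, adjusted p = 0.225).

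TIAM1 and RAC1 did not pass the test. Gene counts measure neither methylation of the TIAM1 protein nor the activity of RAC1, so these tests bear on messenger RNA alone. TIAM1 (ENSG00000156299; GRCh38 chromosome 21, 31118416 to 31559977, minus strand, protein-coding gene) had 19.8 ± 2.14 CPM in shNC and 18.5 ± 0.83 in knockdown (SD, n = 3 and 6). Its log2 fold change was -0.10 (SE 0.070, edgeR adjusted p = 0.236). RAC1 (ENSG00000136238; GRCh38 chromosome 7, 6374523 to 6403977, plus strand, protein-coding gene) had 171 ± 4.25 CPM in shNC and 168 ± 3.32 in knockdown (SD, n = 3 and 6), a log2 fold change of -0.02 (SE 0.030, edgeR adjusted p = 0.547). TIAM1 passed the edgeR test when shNC replicate 1 was left out (log2 fold change -0.19, adjusted p = 0.0399) and after removal of GC and length trends (-0.16, adjusted p = 0.0454). The RAC1 value changed sign under 3 alternatives given in the closing section.

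**Figure D1:**
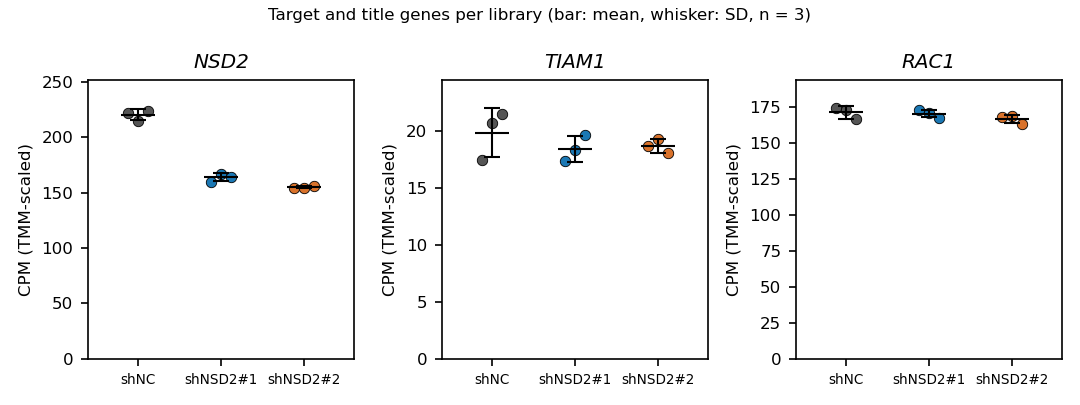
TMM-scaled CPM of NSD2, TIAM1 and RAC1 in each library of shNC, shNSD2#1 and shNSD2#2; points are libraries, bars means and whiskers SD (n = 3). NSD2 means are 220, 164 and 155 CPM, while the TIAM1 and RAC1 libraries of the 3 groups overlap.

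The contrast of shNSD2#1 against shNC asks what the first hairpin changed. Metallothionein genes, which encode small zinc- and copper-binding proteins, rose furthest: MT1M by 3.66, MT1F by 2.61 and MT2A by 2.25 on the log2 scale. NDRG1, a stress-responsive gene induced by low oxygen, fell by 3.00 and ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell by 2.75. FGFBP1, a secreted carrier of fibroblast growth factors, fell by 1.85. In all, 6798 of 16376 genes were called by edgeR, 3455 higher and 3343 lower, with a median absolute log2 fold change of 0.32. The split depends on the scaling, and was 2587 higher and 4231 lower with library sizes alone. An absolute log2 fold change of at least 1 was reached by 429 of them, 162 higher and 267 lower.

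The contrast of shNSD2#2 against shNC repeats the question with the second hairpin. MT1M rose by 3.59, GNG13, a G protein gamma subunit, by 2.40 and MYH3, the embryonic myosin heavy chain, by 2.27 on the log2 scale. ANGPTL4 fell by 2.89 and FGFBP1 by 2.39. The edgeR test called 7750 genes, 3912 higher and 3838 lower, with a median absolute log2 fold change of 0.34. The split was 3295 higher and 4337 lower with upper quartile factors, and 3225 higher and 2036 lower by limma on log2(TPM + 1). An absolute log2 fold change of at least 1 was reached by 575 of them, 212 higher and 363 lower.

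The mean of both hairpins against shNC asks which genes follow the knockdown label. Of the 10 genes that rose furthest with both hairpins, 5 were metallothioneins: MT1M (log2 fold change 3.63, SE 0.050), MT1F (2.61, SE 0.056), MT2A (2.21, SE 0.035), MT1E (2.21, SE 0.035) and MT1X (1.98, SE 0.040). MT2A went from 175 CPM in shNC to 813 CPM in knockdown. These genes are near-identical paralogs, so the division of reads among them is uncertain. The remaining 5 were GNG13 (2.28), MYH3 (2.14), DCAF4L1 (1.75), HFM1, a meiotic DNA helicase (1.66, SE 0.40), and NLGN3, a synaptic adhesion protein (1.56). HFM1 had 13.4 CPM in shNC replicate 1 against 58.4 and 57.7 in the other shNC libraries.

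The 10 genes that fell furthest with both hairpins included ANGPTL4 (log2 fold change -2.82, SE 0.079), NDRG1 (-2.65, SE 0.33), MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210 (-2.07, SE 0.14), and ANKRD37 (-2.07, SE 0.42). They also included FGFBP1 (-2.12), PRRT2, a presynaptic membrane protein (-1.96), the long noncoding RNA LNCPRESS2 (-1.65), CXCR4, the receptor of the chemokine CXCL12 (-1.65), and NAT16 (-1.63). FGFBP1 went from 182 to 42.8 CPM, and ANGPTL4 from 25.8 to 3.64 CPM. NDRG1 stood at 23.7 CPM in shNSD2#2 replicate 3 and at 6.99 to 8.35 CPM in the other 5 knockdown libraries. ANKRD37 stood at 7.68 CPM in that library and at 1.80 to 2.78 CPM in the other 5.

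The edgeR test of the mean called 8237 genes (50.3% of those tested), 4113 higher and 4124 lower, and the median absolute log2 fold change of the called genes was 0.31. Other settings shifted this split, to 3505 higher and 4659 lower with upper quartile factors, 3453 and 4703 with library sizes alone, and 3175 and 2363 by limma on log2(TPM + 1). With both hairpins separately, 5712 genes were called in the same direction, 2928 higher and 2784 lower, and 21 in opposite directions. Independent lists of these sizes would share 825 higher and 783 lower genes. In 20 simulations, all 9 libraries were redrawn from 1 mean per gene, with both simulated hairpin groups compared with the same simulated controls. There, 0.3 genes on average and at most 1 gene were called with both. The simulations hold no offset between groups, so they cannot tell a shared effect of the hairpins from a batch that follows the groups. Across genes, which are not independent replicates, the log2 fold changes of the hairpins had r = 0.811 against a simulated mean of 0.490, and a covariance of 0.170 against 0.0302, a difference of 0.140. The 3 shNC libraries cannot be split into parts of at least 2 libraries, and part of the excess may come from the shared controls.

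**Figure D2:**
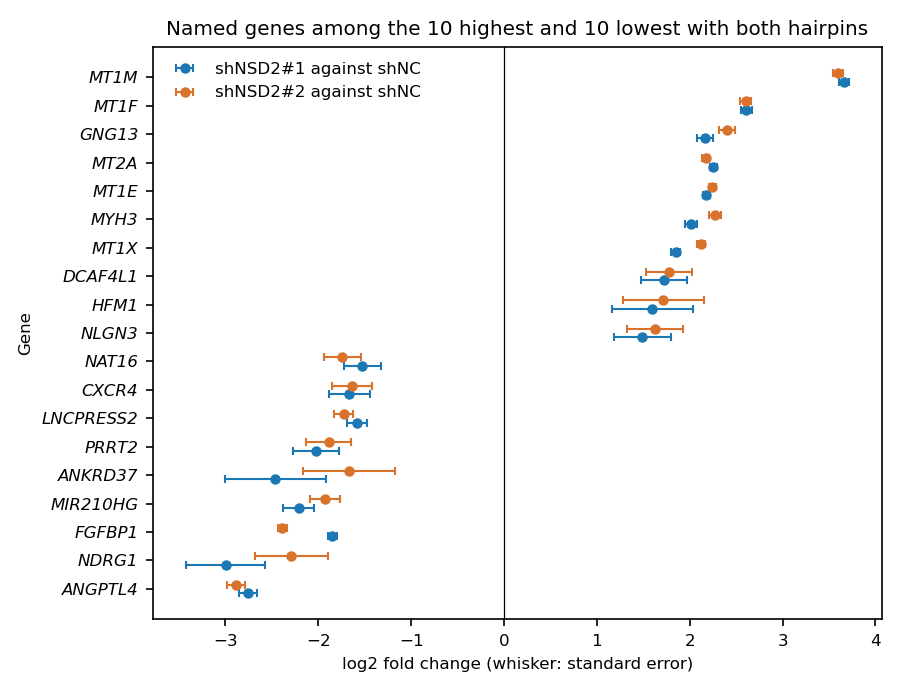
log2 fold change against shNC (horizontal axis, whiskers are standard errors) of the genes named above among the 10 highest and 10 lowest called with both hairpins; blue points are shNSD2#1 and orange points shNSD2#2. MT1M lies at 3.66 and 3.59, and ANGPTL4 is the lowest by the mean of both, at -2.82.

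Gene lists were compared with the other tested genes for the mean of both hairpins, and camera called 2 lists higher and 11 lower. With an estimated correlation 1 of these calls was kept, that of cholesterol and fatty acid synthesis. The estimated correlation of the YAP and TEAD, type I interferon and NF-kB lists was -0.0069, -0.0048 and -0.00016, below the preset 0.01. A higher correlation between genes is therefore not what ended the calls of those lists. Counts adjusted over the list alone are given where they differ from those over all genes, which was so for 8 lists. Of the genes of hypoxia and glycolysis, 31 of 35 fell and the other 4 were not called. ANGPTL4, BNIP3L, a mitophagy receptor (-1.40, SE 0.050), PDK1, a kinase that inhibits pyruvate dehydrogenase (-1.07, SE 0.044), and PFKL, the liver phosphofructokinase (-0.64, SE 0.037), had the smallest adjusted p. The list median was -0.63 (camera adjusted p = 1.07e-13, and adjusted p = 0.173 with an estimated correlation). Its level lay at -0.42 in shNSD2#2 replicate 3 and between -0.71 and -0.61 in the other 5 knockdown libraries.

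Genes of cholesterol and fatty acid synthesis fell as well, 26 of 31, with the other 5 not called. SCD, the stearoyl-CoA desaturase, went from 1002 to 515 CPM (log2 fold change -0.96, SE 0.026), and INSIG1, a feedback regulator of sterol synthesis, from 754 to 411 CPM (-0.88, SE 0.026). ACSS2, a cytosolic acetyl-CoA synthetase, fell by 1.31. The list median was -0.34 (camera adjusted p = 1.62e-10, and adjusted p = 0.0279 with an estimated correlation). Of the unfolded protein and ATF4 response list, 22 of 29 fell and 3 rose, with a median of -0.33 (camera adjusted p = 2.20e-06, and adjusted p = 0.173 with an estimated correlation). It was led by the endoplasmic reticulum chaperones HSPA5 (-0.46, SE 0.026), PDIA4 (-0.46) and CALR (-0.43), with the serine synthesis enzyme PHGDH (-0.46).

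The 13 mitochondrially encoded messenger RNAs fell, with a median of -0.67 (camera adjusted p = 3.96e-10, and adjusted p = 0.179 with an estimated correlation). MT-CYB went from 2363 to 1136 CPM, MT-ND4 from 8293 to 4145 CPM and MT-ND5 from 8025 to 4774 CPM, while MT-ND3 fell by 0.67. As a share of counts in named genes, these messenger RNAs made up 6.81% in shNC and 4.54% in knockdown (exact permutation p = 0.0119, the smallest the design can give, n = 3 and 6). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 went the other way, from 1.24% to 1.91%, with the same exact permutation p of 0.0119. Cytosolic ribosomal RNA shares moved in the same direction, from 4.22% to 6.59% for 5.8S rRNA genes and from 2.74% to 4.58% for the clone-based genes at the ribosomal DNA, with an exact permutation p of 0.0119 each. These shares separate knockdown from shNC completely, so any difference between knockdown and shNC described here goes along with them.

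Nuclear genes of oxidative phosphorylation fell in 17 of 32 cases, with the other 15 not called, and a smaller median of -0.10 (camera adjusted p = 4.56e-04, and adjusted p = 0.394 with an estimated correlation). With log2(TPM + 1) this median was -0.04 (camera adjusted p = 0.0197). SDHA, a subunit of succinate dehydrogenase, fell by 0.49, and CYC1, COX5A and NDUFV1 had log2 fold changes of -0.44, -0.34 and -0.25. Cytosolic ribosomal protein genes had a median of -0.12, with 25 of 36 lower and 1 higher (26 and 1 adjusted over the list alone; camera adjusted p = 1.77e-04, and adjusted p = 0.519 with an estimated correlation). Their median was -0.07 after removal of GC and length trends (camera adjusted p = 0.0489) and -0.05 with log2(TPM + 1). RPL3 fell by 0.34, RPL13 by 0.32, RPL4 by 0.27 and RPLP0 by 0.22.

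**Figure D3:**
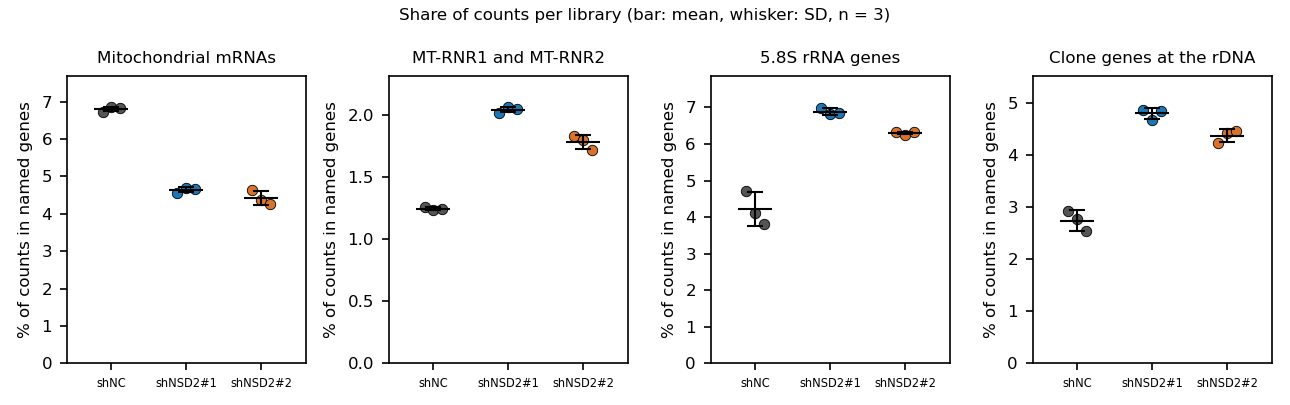
Percent of counts in named genes taken by mitochondrial messenger RNAs, MT-RNR1 and MT-RNR2, 5.8S rRNA genes and clone-based genes at the ribosomal DNA, per library; bars are means and whiskers SD (n = 3). The mitochondrial messenger RNAs average 6.81% in shNC and 4.54% in knockdown, and the 5.8S share 4.22% and 6.59%.

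In each list tied to adhesion, invasion and the epithelial state, more genes fell than rose. Of the mesenchymal and epithelial-mesenchymal transition list, 9 of 15 fell and 1 rose (11 and 1 adjusted over the list alone). FN1, fibronectin, fell by 0.70, LOX, a collagen cross-linking oxidase, by 0.92, COL3A1 by 0.72 and MSN, moesin, by 0.29. The list median was -0.30 (camera adjusted p = 9.61e-04, and adjusted p = 0.173 with an estimated correlation), and -0.48 without shNSD2#2 replicate 3. Epithelial junction genes fell in 18 of 33 cases and rose in 3, with a median of -0.16 (camera adjusted p = 0.00507, and adjusted p = 0.329 with an estimated correlation), and of -0.10 with log2(TPM + 1). KRT19 went from 1022 to 694 CPM, KRT8 from 4947 to 4132 CPM, the desmosomal protein DSP fell by 0.31 and the tight junction protein CLDN1 by 0.53.

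Matrix proteases and inhibitors fell in 13 of 24 cases and rose in 3 (14 and 3 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.0108, and adjusted p = 0.241 with an estimated correlation). After removal of GC and length trends the median was -0.07 and this call ended (camera adjusted p = 0.0700); with log2(TPM + 1) it was -0.09. ADAM10, a membrane sheddase, fell by 0.56, heparanase HPSE by 0.58, cathepsin CTSD by 0.40 and MMP15 by 0.39. Integrin and focal adhesion genes fell in 12 of 33 cases and rose in 3, and the list was not called by camera (median -0.07, adjusted p = 0.0715; lower by fry, adjusted p = 0.00131). ITGA3 fell by 0.54, ITGA1 by 0.42 and PXN, paxillin, by 0.35, while the laminin chain LAMA3 rose by 0.73. The integrin list passed camera under 6 alternatives, among them without shNC replicate 2 (adjusted p = 0.0356) and without shNSD2#2 replicate 3 (adjusted p = 0.0472), while with log2(TPM + 1) its median was -0.01 (adjusted p = 0.306).

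Of 35 tested Rac1 pathway genes, the list nearest to the title of the series, 12 rose and 5 fell, with a median of 0.04 (camera adjusted p = 0.2998; higher by fry, adjusted p = 0.00279). This median turned to -0.04 after removal of GC and length trends (camera adjusted p = 0.834), and was 0.005 with upper quartile factors and 0.003 with library sizes alone. Fry called 20 of the 25 lists tested, so its call does not set the Rac1 list apart. These messenger RNA levels do not measure the activity of the pathway. The guanine nucleotide exchange factors TRIO and ECT2 rose by 0.31 and 0.27, the Ras and Rac exchange factor SOS1 rose by 0.29, and ABI2, a subunit of the WAVE complex, fell by 0.45. In the TPM values the log2 fold change of SOS1 was -0.03 (limma adjusted p = 0.778). RhoA and actomyosin genes fell in 16 of 33 cases and rose in 5, with a median of -0.07 (camera adjusted p = 0.168; lower by fry, adjusted p = 0.00237), and of -0.008 with log2(TPM + 1). The myosin heavy chain MYH9 fell by 0.29, RHOC by 0.37 and the calponin CNN3 by 0.51, while the formin DIAPH1 rose by 0.17.

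Among H3K36 and H3K27 methylation enzymes, 8 of 25 rose and 5 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.349; higher by fry, adjusted p = 0.0390). The list's median of 0.05 turned to -0.01 after removal of GC and length trends (camera adjusted p = 0.820). SETD2, which trimethylates H3K36, rose by 0.45, and the H3K36 methyltransferases ASH1L and NSD1 rose by 0.41 and 0.36, while NSD2 itself is a member and fell. Of 18 neighbours of NSD2 at 4p16.3, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.529). TMEM129 fell by 0.83 and SLBP by 0.22, while NAT8L rose by 0.39 and RNF4 by 0.24.

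Mitotic genes rose. Of the G2/M and mitosis list, 27 of 36 rose and the other 9 were not called (28 rose adjusted over the list alone), with a median of 0.19 (camera adjusted p = 2.12e-07, and adjusted p = 0.173 with an estimated correlation). The mitotic kinase AURKA rose by 0.56, ASPM by 0.48, the kinesin KIF23 by 0.47 and anillin, ANLN, by 0.41. G1/S and DNA replication genes split, 13 higher and 11 lower of 38 (13 and 12 adjusted over the list alone; camera adjusted p = 0.762). POLE rose by 0.45, POLA1 by 0.31 and CDC6 by 0.28, while the licensing factor CDT1 fell by 0.30. Of 12 replication-dependent histone genes 3 rose and the other 9 were not called (camera adjusted p = 0.306; higher by fry, adjusted p = 0.0307), and the list's median of 0.22 turned to -0.006 with log2(TPM + 1). Those that rose were H2BC12 (0.35), H2AC6 (0.42) and H2BC4 (0.90), and H1-2 had a log2 fold change of -0.25 (edgeR adjusted p = 0.0532). H1-2 passed the edgeR test under 6 alternatives, among them library sizes alone (-0.29, adjusted p = 0.0299) and without shNC replicate 1 (-0.30, adjusted p = 0.0471). Histone genes are near-identical copies whose reads the counting can divide.

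YAP and TEAD targets rose in 10 of 18 cases and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0198, and adjusted p = 0.173 with an estimated correlation). The ectonucleotidase NT5E rose by 1.07, CRIM1 by 0.29 and AMOTL2 by 0.26, while F3, tissue factor, fell by 0.56. Of 24 TGF-beta and SMAD targets 9 fell and 3 rose (camera adjusted p = 0.190; lower by fry, adjusted p = 0.00438), among them TGFB2, which fell by 0.63, SERPINE2 by 0.48, TGFB1 by 0.44 and ID1 by 0.19. The median of the TGF-beta list was -0.12, and -0.03 after removal of GC and length trends. The ID1 call ended after removal of GC and length trends (-0.03) and with both hairpins fitted as one group (-0.18, edgeR adjusted p = 0.0697). ERK and MAPK output genes fell in 10 of 27 cases and rose in 5 (camera adjusted p = 0.168, and 0.0213 without shNSD2#2 replicate 3). CCND1, a D-type cyclin, rose by 0.42, while PHLDA1 fell by 0.30, the feedback inhibitor SPRY2 by 0.36 and ETV1 by 0.62.

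For the mean of both hairpins, interferon and inflammatory genes were lower, while camera called neither list with shNSD2#1 alone (adjusted p = 0.0817 and 0.107) and both with shNSD2#2 alone (adjusted p = 0.0101 and 0.0119). Type I interferon response genes fell in 16 of 34 cases and rose in 3, with a median of -0.20 (camera adjusted p = 0.0250, and adjusted p = 0.173 with an estimated correlation). IFIT2 went from 33.7 to 11.5 CPM (-1.55, SE 0.068), and OASL, IFIT3 and IFIT1 fell by 0.99, 0.89 and 0.83. NF-kB and inflammatory genes fell in 8 of 20 cases and rose in 2, with a median of -0.21 (camera adjusted p = 0.0198, and adjusted p = 0.173 with an estimated correlation). The chemokine CXCL8 fell by 1.40, PTGS2, the inducible cyclooxygenase, by 1.29, NFKB2 by 0.68 and CXCL16 by 0.23. The CXCL16 call ended with both hairpins fitted as one group (-0.20, edgeR adjusted p = 0.427), and its log2 fold change with shNSD2#1 was 0.07. The NF-kB list was not called with the filter at 5 CPM (camera adjusted p = 0.0896), and with log2(TPM + 1) the interferon and NF-kB medians were -0.13 and -0.12.

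Of 22 Wnt and intestinal stem cell genes, 6 rose and 7 fell (camera adjusted p = 0.756). The Wnt inhibitor DKK1 fell by 0.59, from 470 to 316 CPM, while CCND1, TNFRSF19 and PROM1 rose by 0.42, 0.57 and 0.38. Of 28 p53 targets, 5 rose and 9 fell (camera adjusted p = 0.613, fry adjusted p = 0.583). The camera direction was lower and that of fry higher, with a median of -0.03. AEN and TRIAP1 rose by 0.59 and 0.45, and FDXR and CCNG1 fell by 0.56 and 0.30. Of 8 tested enterocyte and secretory genes, 1 rose and 2 fell (camera adjusted p = 0.2998; lower by fry, adjusted p = 5.29e-04), and the list's median of -0.15 turned to 0.005 without shNC replicate 2 and 0.65 with no filter. SCG2, a secretogranin, fell by 1.01, the carbonic anhydrase CA2 by 0.28 and MUC5AC rose by 0.36, while AGR2 had a log2 fold change of -0.60 (edgeR adjusted p = 0.126).

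Markers of other cell types were near the detection limit or lower. Of 3 tested fibroblast markers 2 fell, COL3A1 and COL1A1 (-0.42, from 7.70 to 5.76 CPM), and ACTA2 stood at 2.45 and 2.62 CPM. Of 3 immune cell markers 1 fell, the lysosomal protein CD68, from 11.8 to 4.29 CPM, while CD74 stood at 1.89 and 1.98 CPM and HLA-DRA at 1.01 and 0.87 CPM. Of 2 endothelial markers 1 fell, ESAM, from 11.3 to 8.98 CPM, and TEK stood at 0.49 and 0.37 CPM. These 3 lists had fewer than 5 tested members and no set test.

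**Figure D4:**
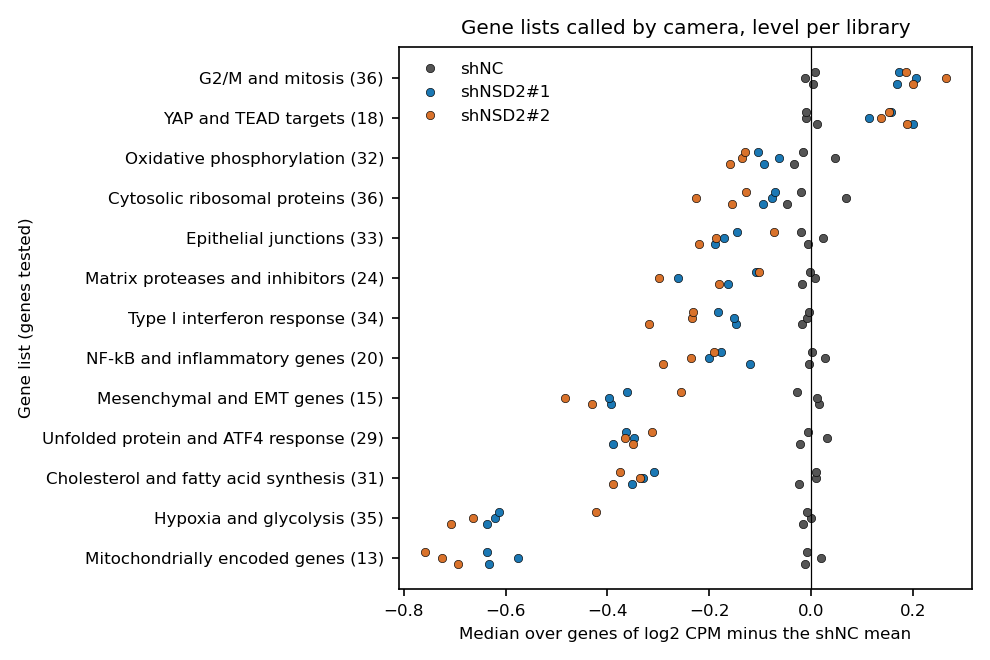
Level of each of the 13 lists called by camera in each library, as the median over the list's genes of log2 CPM minus the shNC mean (horizontal axis), with the number of tested genes in brackets; grey points are shNC, blue shNSD2#1 and orange shNSD2#2. The hypoxia list lies at -0.42 in shNSD2#2 replicate 3 and between -0.71 and -0.61 in the other knockdown libraries.

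The contrast of shNSD2#2 against shNSD2#1 tests the difference between the hairpins' effects. RAB30, a small GTPase of the Golgi, was higher with shNSD2#2 by 0.96 on the log2 scale (SE 0.17), as were PDPK2P (0.86), GOLGA7B (0.85), GDPD3 (0.74) and TMEFF1 (0.64). MSANTD3-TMEFF1 (-0.82), RAB4B, a GTPase of recycling endosomes (-0.62), SHH, the hedgehog ligand (-0.62), TMEM35B (-0.61) and NAPA, a SNAP adaptor of membrane fusion (-0.60), were lower. NAPA stood at 69.9 CPM in shNC and its edgeR adjusted p was 2.29e-08. TMEFF1 and MSANTD3-TMEFF1 overlap and PDPK2P is a pseudogene, so the division of their reads is uncertain.

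The edgeR test called 781 genes between the hairpins (4.77% of those tested), 417 higher and 364 lower with shNSD2#2, with a median absolute log2 fold change of 0.23. With library sizes alone in place of TMM factors, the split was 754 higher and 220 lower. Of the called genes, 13 reached an absolute log2 fold change of 1, 5 higher and 8 lower. The count was 355, 362 and 375 without shNSD2#1 replicate 1, 2 and 3, respectively. Leaving out 1 library ended the calls of PDPK2P, RAB4B, TMEFF1, MSANTD3-TMEFF1, TMEM35B and GOLGA7B, with edgeR adjusted p up to 0.174 and 0.165 (shNSD2#1 replicate 3), 0.247, 0.0509 and 0.0765 (shNSD2#1 replicate 2) and 0.122 (shNSD2#2 replicate 3), in that order. With log2(TPM + 1), the calls of RAB30 (0.87, limma adjusted p = 0.0695), GDPD3 (0.27, limma adjusted p = 0.550) and SHH (-0.36, limma adjusted p = 0.308) ended too.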

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

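The tests of explanations given here, and the choice to compare shares of counts in ribosomal RNA, were made after the results were seen; the comparison of the hairpins was planned.

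Among the genes named in the report, 28 differed between the hairpins by the direct edgeR test. The 10 named for this contrast were RAB30 (log2 difference of shNSD2#2 against shNSD2#1 0.96), PDPK2P (0.86), GOLGA7B (0.85), GDPD3 (0.74), TMEFF1 (0.64), MSANTD3-TMEFF1 (-0.82), RAB4B (-0.62), SHH (-0.62), TMEM35B (-0.61) and NAPA (-0.60). Of the genes that rose or fell furthest with both hairpins, MYH3 (0.26) and MT1X (0.27) rose further with shNSD2#2, and FGFBP1 (-0.54) fell further. Of the adhesion and Rac1 genes, LAMA3 was higher (0.40) and ABI2 (-0.38), MSN (-0.24) and ADAM10 (-0.19) were lower with shNSD2#2. Of the signalling genes, DKK1 (-0.41), CXCL16 (-0.59), ID1 (-0.26), TGFB2 (-0.22), AMOTL2 (-0.15) and SERPINE2 (-0.14) were lower. POLE (0.25) and AEN (0.18) were higher, and PDIA4 (-0.12), HSPA5 (-0.13) and NDUFV1 (-0.14) lower. CXCL16 and ID1 passed the edgeR test against shNC with shNSD2#2 (adjusted p = 4.62e-09 and 5.14e-07) and not with shNSD2#1 (adjusted p = 0.260 and 0.237).

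Camera called 8 lists between the hairpins. The G2/M and mitosis list (adjusted p = 0.00964), the p53 targets (adjusted p = 0.0116) and the H3K36 and H3K27 methylation enzymes (adjusted p = 0.0401) were higher with shNSD2#2. Type I interferon response genes (adjusted p = 0.0167), NF-kB and inflammatory genes (adjusted p = 0.0359), oxidative phosphorylation genes (adjusted p = 0.00893), cytosolic ribosomal protein genes (adjusted p = 1.83e-07) and mitochondrially encoded genes (adjusted p = 3.84e-05) were lower with it. With an estimated correlation, adjusted p for these 8 lists ran from 0.236 to 0.672.

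The number of genes called was compared with that from other groupings of the same libraries. For shNSD2#1 against shNC, shNSD2#2 against shNC and shNSD2#2 against shNSD2#1, the real grouping gave 6798, 7750 and 781 genes and the highest of the others 0. The real grouping was in each case the 1 split of 10 with as many genes, and 10 splits are too few for a share under 0.05. For knockdown against shNC, fitted as a pair of groups, the real grouping gave 7588 genes and the highest of the other 83 splits, which set shNSD2#2 apart, gave 69. The real grouping was the 1 split of 84 that reached its count, the smallest share this design can give. That argues against a random division of these libraries. The other splits mix libraries of different groups, so the comparison cannot tell the knockdown from a batch that follows the groups.

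Counts outside the comparisons also differed between the groups. The loci without a gene name held 3.78% of counts in shNC and 6.33% in knockdown (exact permutation p = 0.0119, the smallest the design can give, n = 3 and 6), and were higher in 6 of 6 knockdown libraries. The most abundant of them, 6028 bases long, held 1.83% in shNC and 3.97% in knockdown.

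The shares of ribosomal RNA rose in the knockdown libraries while the 13 mitochondrially encoded messenger RNAs fell. Dilution by ribosomal RNA reads is argued against as the whole cause of the fall: their share of all counts fell by 0.63 on the log2 scale, of which dilution by ribosomal RNA genes, ribosomal DNA clone genes and unnamed loci gives 0.12, and as a share of the remaining counts they still changed by -0.51, against a range of at most 0.12 within a group. A loss of mitochondrial transcripts of every kind cannot be told apart, since the MT-RNR1 and MT-RNR2 share rose with the other ribosomal RNA (log2 fold change of their ratio -0.069, with a range up to 0.25 within a group) and so may follow its carry-over. A library preparation batch that follows the groups cannot be told apart from the knockdown either: 0 shNC libraries lay inside the knockdown range of the 5.8S share, and the labels name no batch. An effect of the lower NSD2 level stays open on the same grounds, and was not tested.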

How the results depend on the processing

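NSD2 does not reach an absolute log2 fold change of 1, and under the other alternatives it was called lower, with a log2 fold change from -0.55 (GC and length trends removed) to -0.41 (log2(TPM + 1)). Without 1 library, 7008 to 8457 genes were called for the mean of both hairpins and 4884 to 5819 with both in one direction, and camera called 13 to 15 lists. The fold threshold ends the call of 97 of the 128 called genes taken by the naming rule. Of the genes named, at most 12 lost their call under any one of the other alternatives (either TPM test) and at most 2 gained one; with log2(TPM + 1), MUC5AC, CDT1 and COL1A1 were among the 12 (limma adjusted p = 0.108, 0.0787 and 0.137). The filter at 5 CPM and the removal of mitochondrially encoded genes give no value for the genes they leave out. With TPM values, limma on log2(TPM + 1) called 4010 genes for shNSD2#1 against shNC, 75 between the hairpins and 3304 with both in one direction, and on log2(TPM + 0.1) it called 4002, 70 and 3292. An absolute log2 fold change of at least 1 left 429, 575, 496 and 13 genes in the 4 contrasts and 282 with both hairpins, by its own construction. Camera with an estimated correlation called 1 list and fry called 20, against 13 in the report. Of other lists not called, the median turned sign for the neighbours of NSD2 (-0.069 to 0.022 after removal of GC and length trends) and for G1/S and DNA replication (0.019 to -0.013 with upper quartile factors). Between the hairpins, the count ran from 355 to 907 genes when 1 library was left out. Signs turned for RAC1, called in no setting named here (0.0038 with either pseudocount, 0.0083 without GC and length trends), SOS1 (-0.031 and -0.032 with a pseudocount of 1 and 0.1) and CD74 (-0.025 without shNSD2#1 replicate 2, in a range up to 0.205 without 1 library), and the cause was not tested. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated between -0.06 and 0.05. With the replicate number as a block the counts were 6546, 7521, 8044 and 586, and 5510 with both hairpins; TMEFF1 alone of the genes named lost its call. Across 13180 genes, log2 fold change and GC content had a Spearman correlation of -0.26, and 0.04 after offsets. Of the 8237 genes called in the report, 6836 were among the 8312 then called, 6814 of them in the same direction. TPM values keep no depth, and genes changed by 0.3 on the log2 scale were recovered less often than larger changes in simulated counts.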

Other observations

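The tests of gene ontology terms, those of explanations for the hypoxia list and of paralog reads, and the metallothionein family itself, were chosen after the results were seen. The tests on SLC39A10 and on the glucocorticoid genes were written down before those genes were looked at.

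Gene ontology terms from the deposited annotation, with 15 to 300 tested genes each, were compared by camera for the mean of both hairpins. Of 1590 terms, 44 were called higher and 25 lower, and 0 of these 69 calls held with an estimated correlation. Genes of RNA handling in the nucleus led the higher terms. Of 285 genes of RNA splicing, 154 rose and 21 fell (median 0.13, camera adjusted p = 1.20e-05, and adjusted p = 0.489 with an estimated correlation). Of 110 genes of ribosome biogenesis, 67 rose and 14 fell (median 0.19, camera adjusted p = 2.25e-05, and adjusted p = 0.489 with an estimated correlation). Of 179 genes of rRNA processing 100 rose and 30 fell, and of 33 genes of transcription initiation from RNA polymerase I promoters 23 rose and 3 fell (camera adjusted p = 3.72e-04 and 0.00184, and adjusted p = 0.489 each with an estimated correlation). The medians of these terms were 0.11, 0.16, 0.15 and 0.17 after removal of GC and length trends, in that order. These terms rose beside cytosolic ribosomal protein genes that fell.

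Genes of epithelial keratinization led the lower terms. Of 53 such genes, 32 fell and 4 rose (median -0.36, camera adjusted p = 6.05e-04, and adjusted p = 0.489 with an estimated correlation). Of 18 genes of the response to fatty acid, 11 fell and 1 rose (median -0.37, camera adjusted p = 0.00647, and adjusted p = 0.489 with an estimated correlation). Of 19 genes of branched-chain amino acid catabolism, 10 fell and 9 were not called (median -0.12, camera adjusted p = 0.0199, and adjusted p = 0.489 with an estimated correlation). After removal of GC and length trends the medians of these lower terms were -0.29, -0.42 and -0.18, in that order.

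Hypoxia and glycolysis genes were lower in 6 of 6 knockdown libraries. One outlying library does not account for this: the list's median was at most -0.585 in the 9 fits without 1 library, and camera called the list in each of them. A trend with GC content and gene length is argued against as the whole cause by a median of -0.59 after its removal. A difference in oxygen or cell density between the cultures may contribute and cannot be told apart from the knockdown: the list's level varied by 0.29 within shNSD2#2, where replicate 3 stood apart, against 0.02 within each other group and a difference of 0.60 between shNC and knockdown, and the labels record neither density nor harvest time. An effect of the lower NSD2 level stays open, as untested.

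Of 14 metallothionein genes with a count, 7 were tested, among them MT1JP at 0.32 CPM in shNC. All 7 rose for the mean of both hairpins, by 0.62 (MT1A) to 3.63 (MT1M) on the log2 scale. Reads shared between paralogs do not account for this: counts summed over the family rose by 2.13 on the log2 scale, from 383 ± 11.4 CPM in shNC to 1673 ± 12.3 in shNSD2#1 and 1667 ± 60.1 in shNSD2#2 (SD, n = 3 each). A glucocorticoid response is argued against, since FKBP5, TSC22D3, PER1, KLF9 and SGK1 had a median log2 fold change of -0.26, with FKBP5, SGK1 and KLF9 lower by the edgeR test (adjusted p = 1.23e-05, 1.77e-11 and 8.84e-11). TSC22D3, at 1.07 CPM in shNC, and PER1 were not called (edgeR adjusted p = 0.679 and 0.558). PER1 stood at 39.2 CPM in shNSD2#2 replicate 3 and at most 19.5 CPM in the other knockdown libraries. Higher free zinc is a candidate explanation that a test on 1 gene leaves open. The zinc importer SLC39A10, which zinc represses through the metal-sensing factor MTF1, fell by 1.06 (edgeR adjusted p = 5.58e-15, lower in 6 of 6 knockdown libraries). This met the prediction that it would be called lower, a weak test, since 4124 of 16376 tested genes were called lower. MTF1 itself rose by 0.42 (edgeR adjusted p = 1.34e-07), so the test cannot tell more zinc from more MTF1. The zinc exporter SLC30A1, chosen after its value was seen, rose by 1.30. The source of any higher zinc (the medium, the virus preparation or the lower NSD2 level) was not tested.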
